A study of Mus musculus with 18 samples.

How the data were processed

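RNA was profiled in 18 libraries of mouse embryonic stem cells and their differentiated progeny, 3 per group, from parental and Oct1 conditional knockout cells at days 0, 3 and 6. The labels describe total RNA extracted with Trizol and a standard Illumina preparation, and do not state whether poly(A) RNA was selected. The deposited table holds a raw count per Ensembl gene and library, with no normalization. The submitters' processing notes list Novoalign without a version, DESeq2 1.10.0 and the mouse genome builds mm10 and GRCm38. The counting tool, annotation release and strand setting are not given in the sources used here. The table holds 25279 genes, of which 25221 identifiers are in GENCODE M21, the source of coordinates and biotypes. Library totals ran from 13704958 to 26995420 counts, and counting error is only part of the spread between libraries.

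Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Genes passing filterByExpr on the 6 groups were kept, 20267 in all, and scaled with TMM factors. A group means model over the 18 libraries was fitted with the robust edgeR quasi-likelihood method, with a biological coefficient of variation of 13.5%. Each contrast was tested with a two-sided F test, and genes with a Benjamini-Hochberg adjusted p under 0.05 were called. The contrasts were cKO against parental at each day and over the mean of days, day 3 against day 0 and day 6 against day 3 in each genotype, and the difference of each time change between genotypes. Levels are CPM from edgeR with TMM effective library sizes.

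A set of 30 gene lists was fixed before the data were examined, as were the contrasts, tests, alternatives and the rule for naming genes. Lists were tested with camera on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the lists of a contrast, and lists with fewer than 4 measured members were not tested. Calls were also counted when adjusted over the list alone. List genes missing from the table were not analysed here. Genes were named by 3 criteria: Pou2f1; the 10 largest called changes each way (5 for time changes) with a mean of at least 5 CPM and groups that did not overlap, a condition dropped for differences of time changes; and, for each list, up to 4 called members with the smallest adjusted p and up to 2 of the most highly expressed members not called. Members of lists with a count of 5 or fewer could also be named, and predicted genes with systematic symbols were left out. Of the genes these criteria allow, 3 are not reported here. Time changes of the genotypes were compared by Pearson and Spearman correlation across genes, with a jackknife over libraries.

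The alternatives were RLE factors, total-count scaling, no low-count filter, at least 1 CPM in 3 libraries, the DESeq2 Wald test, a fit of the libraries of the contrast alone, each library left out in turn, and camera with an estimated correlation or fry for lists. The estimated correlation was 1 value per list over all 18 libraries, the same for every contrast. Tests of protein-coding genes only and of genes outside chromosome 11 were added after the data were seen. The steps were tested on simulated data of 19840 genes: at day 3 edgeR recovered 49.3% of 67 genes changed 1.5 fold, 71.6% of 67 changed 2 fold and 97.0% of 66 changed 4 fold, with 7 unchanged genes called, and DESeq2 recovered 59.7%, 77.6% and 97.0% with 28 unchanged genes called. Camera called the shifted list (adjusted p = 2.02e-24) and 0 of 26 others. The simulated genes varied independently of each other, so this does not test camera on lists whose genes are correlated. A simulated chromosome 11 shift of -0.415 was recovered as -0.387. Sequence shared between genes was measured as the share of 50-base stretches, sampled every 25 bases, found in another gene. Splice forms, single exons and alleles were left out because the table holds gene totals.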

Results

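Bulk RNA was sequenced from mouse embryonic stem cells (ESCs) and from cells derived from them with a protocol that induces mesoderm. Parental cells and cells with a conditional knockout (cKO) of Oct1, the POU-domain transcription factor encoded by Pou2f1, were profiled at day 0, day 3 and day 6 of differentiation. Each of the 6 groups held 3 libraries, 18 in all. Library totals ran from 13704958 to 26995420 counts over 25279 genes, of which 20267 had enough counts to be tested. The labels do not say whether the 3 libraries of a group came from separate cultures, so every p-value here measures only the spread between these libraries. Levels are normalised read counts on the CPM scale of edgeR, given as mean ± SD with n = 3, and log2 fold changes are given ± SE.

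Pou2f1 (ENSMUSG00000026565, chromosome 1, 165865154 to 166002678 on the minus strand of GRCm38) was lower in cKO than in parental libraries at each day. The 9 parental libraries lay between 123 and 142 CPM and the 9 cKO libraries between 62.2 and 95.4 CPM. At day 0 its level was 79.1 ± 14.6 CPM in cKO and 128 ± 5.75 CPM in parental cells, a log2 fold change of -0.70 ± 0.11 (adjusted p = 9.46e-05). At day 3 the change was -0.58 ± 0.11 (adjusted p = 0.0011) and at day 6 it was -0.86 ± 0.11 (adjusted p = 7.91e-06). Counts are summed over the whole gene, so they do not show which exons remained.

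**Figure D1:**
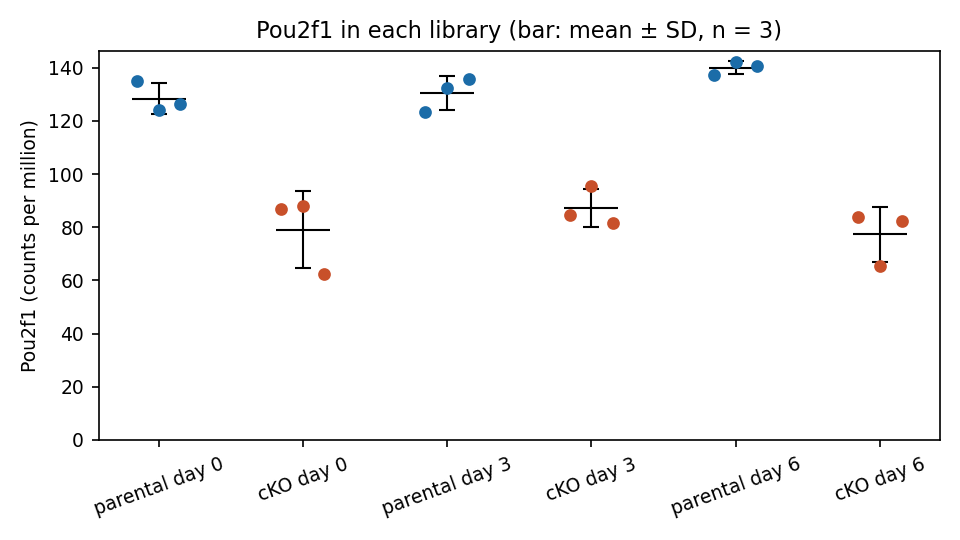
Pou2f1 in CPM in each of the 18 libraries, by genotype and day; the horizontal bar and its whiskers give the mean and SD of the 3 libraries of a group. The parental libraries sit between 123 and 142 CPM and the cKO libraries between 62.2 and 95.4 CPM.

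The first question of the series is how cKO cells differ from parental cells before differentiation. At day 0, genes of the 2-cell embryo were higher in cKO cells and fibroblast and feeder genes lower. The glycolysis and hypoxia list was called downwards too, a call lost with an estimated correlation (adjusted p = 0.86). Of the 13 measured genes of the two-cell-like list, 12 rose and 1 fell, with the same counts adjusted over the list alone. The list was called by camera (adjusted p = 3.79e-06; adjusted p = 0.0431 with an estimated correlation). Zfp352, a retrogene of the 2-cell embryo, reached 11.8 ± 0.283 CPM against 0.898 ± 0.077 CPM in parental cells. Zscan4d and Zscan4c, which act at telomeres, rose by 2.35 ± 0.23 and 2.05 ± 0.22. Zscan4c shares 84.4% of its sampled 50-base stretches with another gene, and Zscan4d 49.4%. How reads shared by several genes, or by overlapping and antisense genes, were counted is not given in the sources used here, so the split of counts among such relatives is uncertain.

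Of 18 measured fibroblast and feeder genes, 11 fell and none rose at day 0, and 12 fell when adjusted over the list alone. Camera called the list (adjusted p = 7.44e-07; adjusted p = 0.00354 with an estimated correlation). The fibrillar collagen gene Col1a2 stood at 58.9 ± 1.31 CPM in cKO and 206 ± 9.63 CPM in parental cells, and Col3a1 changed by -1.82 ± 0.16. Bulk RNA does not show which cells of a culture carried these transcripts. In the glycolysis and hypoxia list 10 of 23 genes fell and none rose, 11 when adjusted over the list alone (adjusted p = 0.00673; adjusted p = 0.86 with an estimated correlation). Pfkp, a phosphofructokinase, changed by -1.26 ± 0.16, and Vegfa, an angiogenic growth factor, by -1.32 ± 0.11. The abundant enzyme genes Pkm (0.14 ± 0.10) and Eno1 (-0.07 ± 0.11) were not called. Mitochondrially encoded mRNA took 1.24% to 1.38% of counts in the cKO day 0 libraries and 2.01% to 2.12% in the parental ones, 4.85% to 4.93% and 5.31% to 5.62% at day 3, and 3.72% to 4.13% and 3.00% to 3.19% at day 6. Ribosomal protein mRNA took 5.84% to 7.26% in the cKO day 0 libraries and 5.25% to 5.38% in the parental ones.

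Camera called neither pluripotency list at day 0. In the naive list 5 of 17 genes rose and 1 fell, and in the general pluripotency list 5 of 14 rose and 1 fell, with adjusted p = 0.67 and 0.218. The test fry, which compares a list with no other genes, called the general list upwards (adjusted p = 0.00122) and not the naive list (0.579). Nanog and Esrrb, both core naive factors, gave 0.11 ± 0.10 and 0.09 ± 0.13 and were not called, while Prdm14 rose by 1.30 ± 0.22 and Dppa3, a maternal-effect gene, fell by 2.32 on the log2 scale. Pou5f1, which encodes Oct4, rose by 0.76 ± 0.23 (adjusted p = 0.0191). In the list of primitive streak and nascent mesoderm 8 of 21 genes rose and none fell (adjusted p = 0.0758, not called), among them Cdx1 (1.64 ± 0.22) and Eomes (1.41 ± 0.31). Lefty1, a Nodal antagonist, fell by 2.34, and Skil, a Smad corepressor, by 0.95, within a TGF-beta, Nodal and BMP list of which 3 of 24 genes rose and 8 fell (adjusted p = 0.67). The FGF targets Etv4 and Spry4 rose by 2.37 ± 0.12 and 1.59 ± 0.17, and 5 of 16 genes of that list rose with none falling (adjusted p = 0.0526).

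Outside the lists, Pou2f3, a paralogue of Pou2f1, stood at 89.2 ± 2.17 CPM in cKO and 8.54 ± 0.901 CPM in parental cells at day 0. The X-linked gene Usp26 (-3.38 ± 0.15), the cytokine receptor gene Crlf2 (-4.52 ± 0.37) and Aass, an enzyme of lysine breakdown (-3.33 ± 0.23), were among the largest decreases. Igfbp4, on chromosome 11, fell by 3.19. In all, 3052 genes were higher and 3350 lower in cKO at day 0, 845 and 979 of them by at least 2-fold. The share of called genes that were higher, 47.7%, was 52.8% with RLE factors or DESeq2, so which direction held more calls depends on scaling. The call of Pou5f1 was lost without parental replicate 1 (adjusted p = 0.0703), without parental replicate 3 (0.0608) and without cKO replicate 3 (0.0793).

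At day 3, camera called the streak, Wnt-response, Hox and naive pluripotency lists lower in cKO and the formative epiblast list higher. None of these calls was kept with an estimated correlation (adjusted p = 0.06 to 0.192). Of 21 measured streak and nascent mesoderm genes, 10 fell and 3 rose, and 13 fell and 3 rose when adjusted over the list alone. Camera called this list (adjusted p = 5.7e-05; adjusted p = 0.138 with an estimated correlation). Cdx2, a regulator of posterior identity, stood at 3.64 ± 1.47 CPM in cKO and 32.0 ± 4.26 CPM in parental cells, and Wnt8a, a Wnt ligand of the streak, at 52.2 ± 15.6 and 197 ± 8.73 CPM. Cdx1 changed by -3.89 ± 0.25 and Nkx1-2 by -1.67 ± 0.15. Fgf8 (-0.58 ± 0.23) was not called and was called without cKO day 3 replicate 1 (-0.81, adjusted p = 0.0436).

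Among 15 Wnt-response genes 9 fell and 1 rose at day 3, 10 and 1 when adjusted over the list alone (adjusted p = 5.94e-05; adjusted p = 0.0684 with an estimated correlation). Sp5 changed by -1.87 ± 0.23 and Axin2, a feedback inhibitor of Wnt signalling that lies on chromosome 11, by -1.17 ± 0.14, whereas the cyclin gene Ccnd1 rose by 0.46 ± 0.05. Outside chromosome 11, 5 of 10 Wnt-response genes fell and 1 rose. In the Hox list 13 of 33 genes fell and none rose, 15 when adjusted over the list alone (adjusted p = 1.49e-06; adjusted p = 0.192 with an estimated correlation). Hoxa3 changed by -2.40 ± 0.29. Hoxb1 (-2.33 ± 0.23) and Hoxb2 (-2.03 ± 0.34) belong to the cluster on chromosome 11, a chromosome whose genes had a median change of -0.39 at this day. Outside chromosome 11, 8 of 23 Hox genes fell and 0 rose.

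Among naive pluripotency genes 11 of 17 were lower in cKO at day 3 and 1 was higher, 12 and 1 when adjusted over the list alone (adjusted p = 1.49e-06; adjusted p = 0.06 with an estimated correlation). Dppa5a stood at 28.2 ± 2.03 CPM against 54.3 ± 4.38 CPM, Zfp42 changed by -1.64 ± 0.11 and Nr5a2 by -2.92 ± 0.20, while Nanog (-0.26 ± 0.10) was not called. Of 12 formative and primed epiblast genes 7 rose and 2 fell, 9 and 2 when adjusted over the list alone (adjusted p = 0.000511; adjusted p = 0.138 with an estimated correlation). Fgf5 reached 64.8 ± 7.71 CPM against 14.3 ± 1.43 CPM, and Otx2, which maintains this state, 23.6 ± 7.65 against 2.49 ± 0.53 CPM. The de novo DNA methyltransferase gene Dnmt3b rose by 0.63 ± 0.09. Foxd3 and the neural proteoglycan gene Ncan rose by 2.38 ± 0.21 and 3.62 ± 0.13, though the neuroectoderm list as a whole was not called (5 of 24 genes rose and 1 fell; adjusted p = 0.128).

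Further lists were called at day 3. Germline genes fell in 7 of 16 cases (adjusted p = 0.00505; adjusted p = 0.311 with an estimated correlation), with Rhox5 at -2.22 ± 0.18 and Hormad1 at -1.77 ± 0.26. Trophoblast genes fell in 5 of 18 cases and rose in 1 (adjusted p = 0.0245; adjusted p = 0.492 with an estimated correlation), and imprinted genes fell in 9 of 24 and rose in 2 (adjusted p = 0.0252; adjusted p = 0.436). Peg10, a member of both, changed by -1.92 ± 0.12. Glycolysis and hypoxia genes fell in 5 of 23 cases, 9 when adjusted over the list alone (adjusted p = 0.0245; adjusted p = 0.648 with an estimated correlation), with Pdk1 at -1.34 ± 0.27. The epithelial junction list was called upwards at a median log2 fold change of 0.29 (adjusted p = 0.0353; adjusted p = 0.814 with an estimated correlation), although none of its 17 genes was called, also when adjusted over the list alone. The Nodal antagonist genes Lefty1 and Lefty2 fell by 1.66 and 2.03 although 6 of 24 genes of the TGF-beta, Nodal and BMP list rose and 4 fell (adjusted p = 0.41).

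In all, 1281 genes were higher and 1904 lower in cKO at day 3, 200 and 644 of them by at least 2-fold. Chromosome 11, over its genes of at least 5 CPM, held 10 of the higher and 565 of the lower calls. The fit of the 6 day 3 libraries alone called 5874 genes. The glycolysis call was lost without parental day 3 replicate 2 (adjusted p = 0.222), the trophoblast call without cKO day 3 replicate 3 (0.0508), the imprinted call without parental or cKO day 3 replicate 1 (up to 0.0599), and the epithelial junction call without parental replicate 2 (0.0854), parental replicate 3 (0.0602), cKO replicate 1 (0.0934) or cKO replicate 2 (0.0745).

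**Figure D2:**
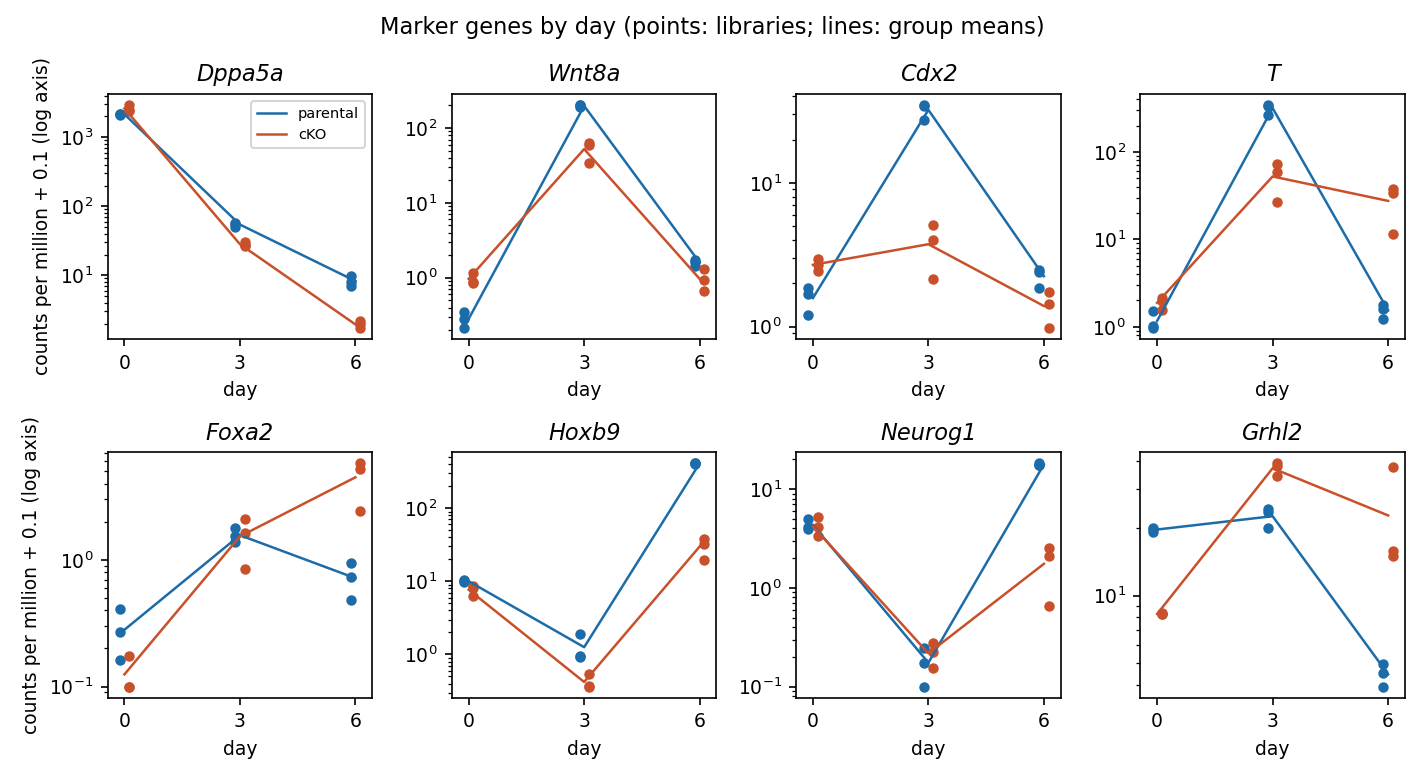
CPM of 8 marker genes at days 0, 3 and 6 on log axes, with a small constant added so that values of 0 can be drawn; points are libraries (blue parental, orange cKO) and lines join group means. Cdx2 reached 32.0 CPM in parental and 3.64 CPM in cKO libraries at day 3, and Hoxb9 410 and 29.8 CPM at day 6.

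At day 6, Hox genes and genes of neuroectoderm and neurons were lower in cKO cells, and genes of endoderm, epithelial junctions, the fibroblast and feeder list and p53 targets were higher. Of these lists, extraembryonic endoderm and fibroblast and feeder alone kept their call with an estimated correlation. Of 33 measured Hox genes, 25 fell and 3 rose, 26 and 3 when adjusted over the list alone (adjusted p = 3.17e-05; adjusted p = 0.194 with an estimated correlation). Hoxb9, on chromosome 11, stood at 29.8 ± 9.12 CPM in cKO and 410 ± 2.41 CPM in parental cells, and Hoxc4, on chromosome 15, at 6.05 ± 3.26 and 102 ± 7.11 CPM. Hoxc8 changed by -2.73 ± 0.28, while the anterior gene Hoxa2 (-0.07 ± 0.32) was not called. With chromosome 11 left out, 16 of 23 Hox genes fell and 3 rose. Medians of the Hox list against parental day 6 were -1.36, -2.57 and -1.38 in cKO replicates 1, 2 and 3. Without replicate 2, 25 genes fell and 1 rose.

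Of 24 neuroectoderm and neuron genes 15 fell and 3 rose at day 6, 16 and 4 when adjusted over the list alone (adjusted p = 0.00281; adjusted p = 0.294 with an estimated correlation). The proneural gene Neurog1 stood at 1.65 ± 0.973 CPM in cKO and 17.6 ± 0.465 CPM in parental cells, the neuronal microtubule gene Dcx at 2.24 ± 1.36 and 18.2 ± 1.35 CPM, and the progenitor gene Dbx1 at 3.74 ± 2.64 and 113 ± 8.55 CPM. In the Notch-response list 8 of 11 genes fell and 2 rose (adjusted p = 0.0256; adjusted p = 0.397 with an estimated correlation). Hes5, a Notch effector, changed by -3.67 ± 0.41 and the ligand gene Dll1 by -2.51 ± 0.27. Medians of the Notch list against parental day 6 were -0.86, -2.15 and -0.63 in cKO replicates 1, 2 and 3. Without replicate 2, 8 genes fell and 2 rose, with a median log2 fold change of -0.69. Skeletal muscle genes were not called as a list (2 of 12 rose and 5 fell, with a median of 0.17 and a mean of -0.85; adjusted p = 0.313). Their median was -0.28 without cKO day 6 replicate 2, with 4 higher and 4 lower. Pax7, a member that marks muscle progenitors and dorsal neural cells, stood at 5.0 ± 3.08 CPM in cKO and 55.7 ± 1.78 CPM in parental cells. Myogenin (Myog) stood at 0.171 ± 0.0282 and 6.45 ± 0.866 CPM.

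Streak and nascent mesoderm genes, lower in cKO at day 3, were on balance higher at day 6. Of 21 genes 11 rose and 3 fell, 11 and 4 when adjusted over the list alone (adjusted p = 0.0174; adjusted p = 0.247 with an estimated correlation). T (brachyury), the T-box factor of the streak, stood at 27.4 ± 14.1 CPM in cKO and 1.44 ± 0.285 CPM in parental cells at day 6, after 52.3 ± 23.4 and 317 ± 45.3 CPM at day 3. Sp5 rose by 2.26 ± 0.26 and Fgf8 by 2.85 ± 0.36. The presomitic list was not called, with 8 of 23 genes higher and 5 lower (adjusted p = 0.31), among them Pcdh19 (1.35 ± 0.14) and Lfng (-1.68 ± 0.15). Its median against parental day 6 was 0.74, -0.60 and 0.63 in cKO replicates 1, 2 and 3, and without replicate 2, 12 genes were higher and 5 lower. Lateral plate genes rose in 5 of 16 cases and fell in 2 (adjusted p = 0.0788), Bmp4 by 2.73 ± 0.24.

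In the extraembryonic endoderm list 14 of 20 genes rose in cKO at day 6 and none fell (adjusted p = 1.23e-07; adjusted p = 0.00135 with an estimated correlation), including Dab2, an endocytic adaptor, at 90.4 ± 7.07 CPM against 31.2 ± 1.6 CPM, Apoe (1.40 ± 0.10) and the laminin gene Lamb1 (1.34 ± 0.14). In the definitive endoderm list 7 of 12 genes rose and 2 fell (adjusted p = 0.00239; adjusted p = 0.194 with an estimated correlation). Foxa2, a pioneer factor of endoderm, stood at 4.38 ± 1.78 CPM against 0.617 ± 0.233 CPM, and Sox17 rose by 2.23 ± 0.39. Endothelial and blood genes rose in 10 of 15 cases and fell in 2, 11 and 2 when adjusted over the list alone (adjusted p = 0.00334; adjusted p = 0.247 with an estimated correlation), with the VEGF receptor gene Flt1 up by 1.69 ± 0.15. The median of this list against parental day 6 was 1.40 in cKO replicates 1 and 3 and -0.13 in replicate 2.

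Epithelial junction genes rose in 16 of 17 cases at day 6 and none fell (adjusted p = 5.08e-09; adjusted p = 0.222 with an estimated correlation). Grhl2, a regulator of epithelial identity, rose by 2.37 ± 0.27, the splicing factor gene Esrp1 by 1.98 ± 0.23 and the tight junction gene Ocln by 1.80 ± 0.24. The list's median against parental day 6 was 1.25, 2.61 and 1.39 in cKO replicates 1, 2 and 3. Fibroblast and feeder genes rose in 14 of 18 cases and none fell (adjusted p = 6.58e-07; adjusted p = 0.00223 with an estimated correlation), Col1a2 reaching 296 ± 26.1 CPM against 153 ± 4.59 CPM. In the list of epithelial to mesenchymal transition 6 of 13 genes rose and 2 fell (adjusted p = 0.0788), with medians of 0.48, -0.49 and 0.53 in cKO replicates 1, 2 and 3; without replicate 2, 9 rose and 2 fell.

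Among signalling lists at day 6, FGF and ERK targets rose in 12 of 16 cases with none falling, 14 when adjusted over the list alone (adjusted p = 7.6e-06; adjusted p = 0.00223 with an estimated correlation), Etv5 by 0.94 ± 0.08 and Il17rd by 1.03 ± 0.10. In the TGF-beta, Nodal and BMP list 15 of 24 genes rose and 4 fell (adjusted p = 0.00104; adjusted p = 0.014 with an estimated correlation), with Junb, a TGF-beta target, up by 1.25 ± 0.20 and Msx1, a BMP target, at -2.76 ± 0.34. The p53 target list rose in 19 of 21 cases and fell in 1 (adjusted p = 5.27e-08; adjusted p = 0.233 with an estimated correlation), with the death receptor gene Fas up by 2.42 ± 0.36 and Eda2r at -1.77 ± 0.24. Its median was 1.12, and 0.59 without cKO day 6 replicate 2. Stress genes rose in 11 of 20 cases and fell in 1, 13 and 1 when adjusted over the list alone (adjusted p = 0.000108; adjusted p = 0.0721 with an estimated correlation), with the chaperone gene Hspa5 up by 0.83 ± 0.06. Cell cycle genes fell in 14 of 23 cases and none rose (adjusted p = 0.000885; adjusted p = 0.439 with an estimated correlation), with Ccnb2, a cyclin gene of mitosis, at 40.1 ± 4.15 CPM against 80.5 ± 1.84 CPM. The medians of this list were -0.21, -0.68 and -0.16 in cKO replicates 1, 2 and 3, and without replicate 2, 14 genes fell and 2 rose (adjusted p = 0.00721). Naive pluripotency genes were again lower, 13 of 17 falling and 1 rising (adjusted p = 0.000215; adjusted p = 0.0721 with an estimated correlation), with Dppa5a at 1.84 ± 0.227 CPM against 8.17 ± 1.35 CPM.

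Polycomb genes fell in 12 of 20 cases and rose in 1 at day 6, 13 and 1 when adjusted over the list alone (adjusted p = 0.00677; adjusted p = 0.209 with an estimated correlation), and germline genes fell in 9 of 16 and rose in 1 (adjusted p = 0.00186; adjusted p = 0.194). Several Polycomb genes, such as Suz12 (-0.62 ± 0.06) and Pcgf2 (-0.64 ± 0.08), lie on chromosome 11, and the Polycomb call was lost with chromosome 11 left out (adjusted p = 0.113). Wnt response, not called with all genes, was then called (6 of 10 higher, 2 lower; adjusted p = 0.0214; adjusted p = 0.246 with an estimated correlation). Lists not called at day 6 included formative epiblast (6 of 12 higher, 2 lower; adjusted p = 0.0983), glycolysis and hypoxia (2 of 23 higher, 10 lower, and 5 and 9 without cKO day 6 replicate 2; 0.14), general pluripotency (3 of 14 higher, 6 lower; adjusted p = 0.196), Wnt response (8 of 15 higher, 4 lower; 0.0616), trophoblast (7 of 18 higher, 6 lower; 0.246), neural crest (4 of 14 higher, 6 lower; 0.404), two-cell-like (0 of 13 higher, 1 lower; 0.612), imprinted genes (7 of 24 higher, 7 lower, with a median that was positive with RLE factors and negative with total-count scaling; 0.709) and Oct family and cofactors (1 of 11 higher, 6 lower; 0.0983).

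In all, 4036 genes were higher and 5202 lower in cKO at day 6, 1687 and 1803 of them by at least 2-fold, around a median of all genes of -0.09, which total-count scaling moved to -0.16 and RLE factors to -0.02. The share of called genes that were higher, 43.7%, was 50.8% with RLE factors, 50.9% with DESeq2, 53.8% with no low-count filter and 37.0% with total-count scaling. The fit of the 6 day 6 libraries alone, whose spread is not shared with other days, called 5721 genes. The cKO day 6 replicate 2 library stood apart from the other cKO day 6 libraries, with Spearman correlations of 0.961 and 0.963 to them, while these correlated at 0.982. Without it 9462 genes were called. The change of the Wnt ligand gene Wnt10a was 5.35 ± 0.91 with it and 3.41 without it, and that of Cyp1a1, a target of the aryl hydrocarbon receptor, was 5.49 ± 0.92 and 3.35.

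**Figure D3:**
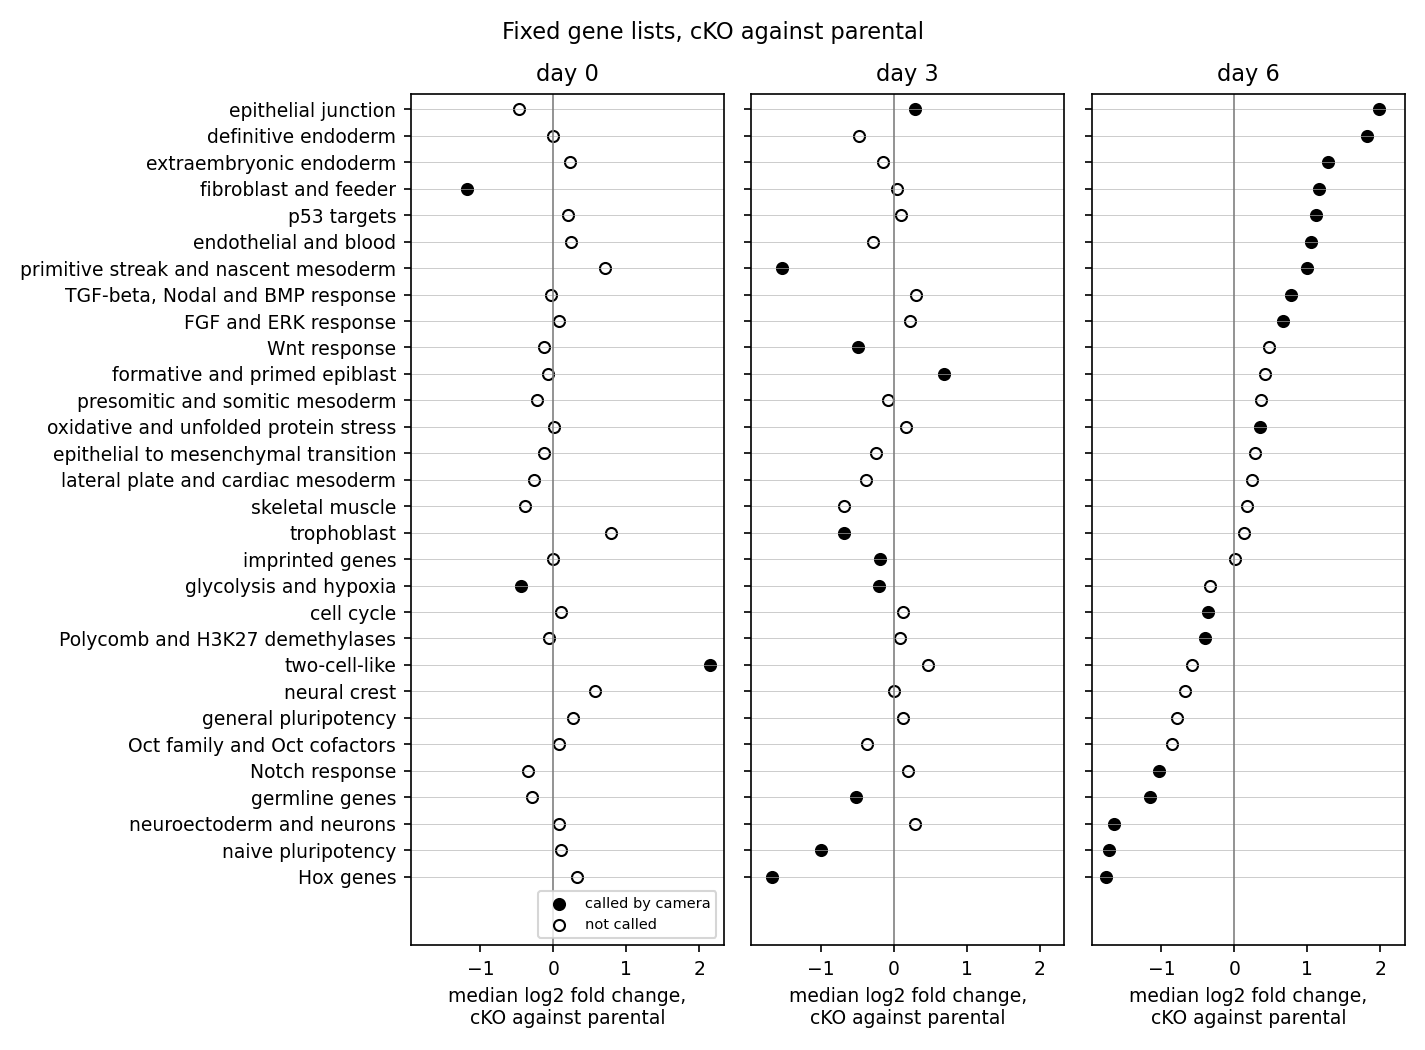
Median log2 fold change of each of the 30 gene lists in cKO against parental at days 0, 3 and 6; filled points mark lists called by camera with the preset correlation. The two-cell-like list lies at 2.14 at day 0, and the Hox list at -1.67 at day 3 and -1.76 at day 6.

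**Figure D4:**
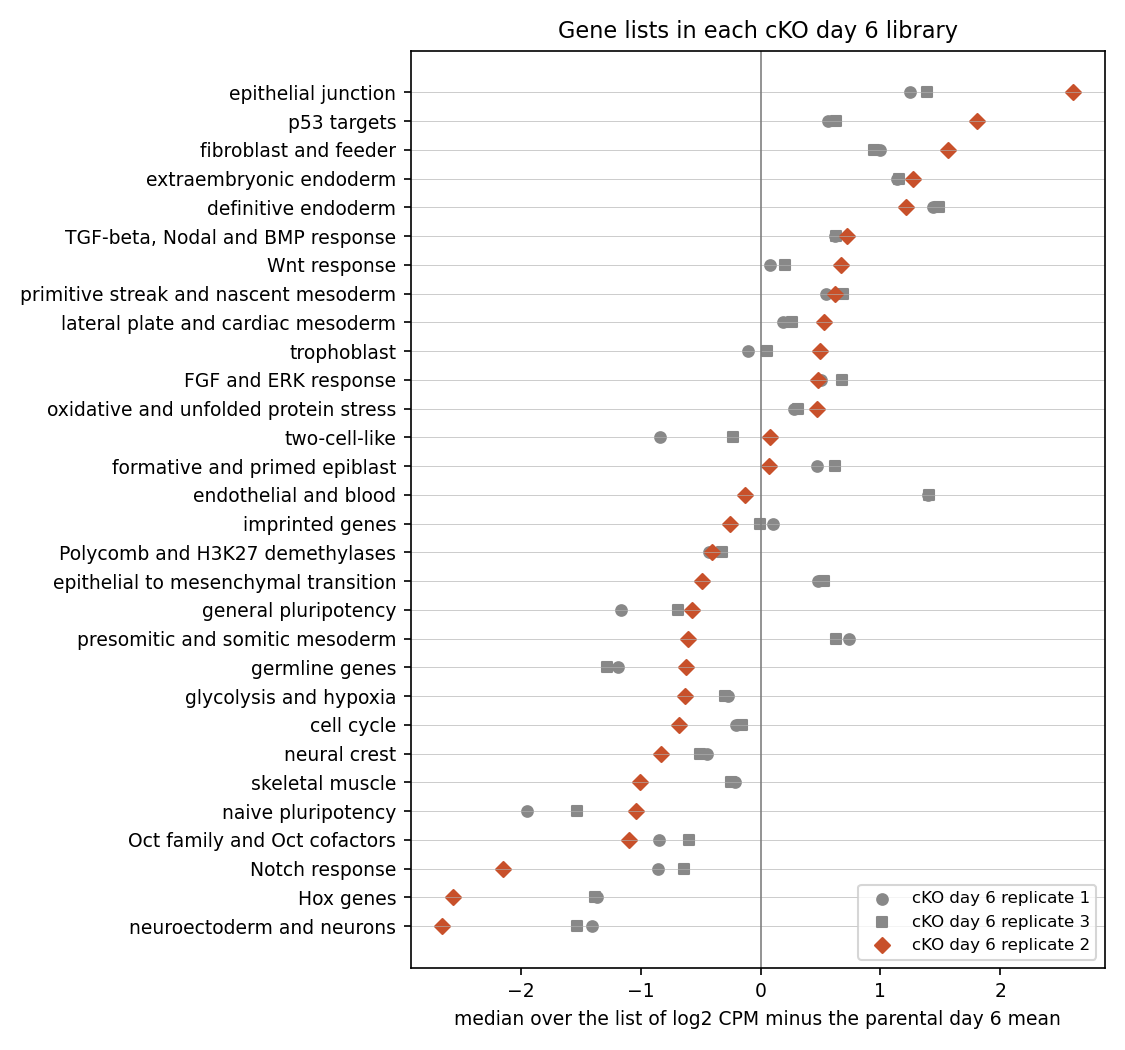
Median over each gene list of log2 CPM minus the parental day 6 mean, for the 3 cKO day 6 libraries (circle, replicate 1; square, replicate 3; orange diamond, replicate 2). Neuroectoderm genes had medians of -1.40, -2.65 and -1.53 in replicates 1, 2 and 3.

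Averaged over the 3 days, 3230 genes were higher and 4075 lower in cKO. The 44.2% higher became 52.7% with RLE factors, 53.4% with DESeq2 and 36.7% with total-count scaling. The genes of chromosome 11 moved together. Their median was -0.38 at day 0, -0.39 at day 3 and -0.49 at day 6, against 0.02, 0.03 and -0.03 for genes of the other autosomes. Over the mean of days 748 of 921 chromosome 11 genes were lower and 34 higher, with a median of -0.43. Trim37 (-0.85 ± 0.05), Brip1 (-0.85 ± 0.06) and Mettl23 (-0.91 ± 0.07), all on chromosome 11, were among the genes lower at each day. Elsewhere the meiosis regulator gene Dmrt1 (-3.02 ± 0.09), the non-coding RNA gene Snhg11 (-1.11 ± 0.04) and the Y-linked demethylase gene Kdm5d (-1.70 ± 0.06) were lower, and the small GTPase gene Rras (1.33 ± 0.08), the netrin receptor gene Unc5b (1.73 ± 0.22) and Wwc2 (1.30 ± 0.14) were higher.

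**Figure D5:**
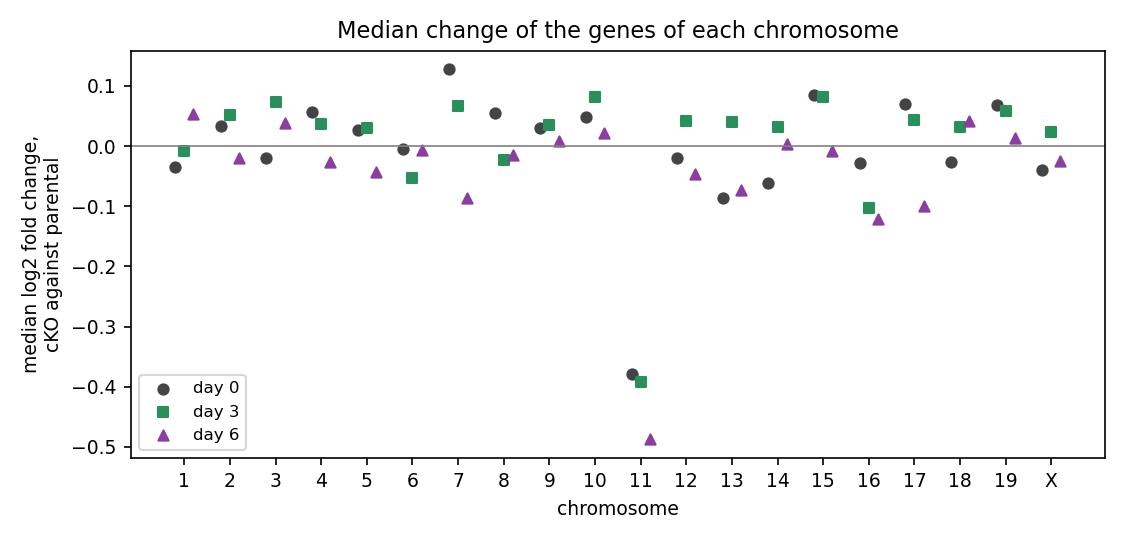
Median log2 fold change of the genes of each chromosome, cKO against parental, at day 0 (circles), day 3 (squares) and day 6 (triangles). Chromosome 11 lies at -0.38, -0.39 and -0.49.

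Called genes overlapped between days more than independence would give. In the same direction at all 3 days, 159 genes were higher where 38.4 would be shared by chance, and 512 were lower where 80.8 would be; 330 of the 512 lie on chromosome 11. Day 0 and day 3 shared 410 higher and 792 lower genes (192.9 and 314.7 by chance), and day 3 and day 6 shared 487 and 1028 (255.1 and 488.7 by chance). The overlap of day 0 and day 6 was nearer to chance, with 773 and 1260 (607.8 and 859.9 by chance). The 330 chromosome 11 genes are among the shared lower genes of each pair of days. The chance values assume independent genes, which a shift of a whole chromosome breaks. In opposite directions, only genes lower at day 0 and higher at day 3 exceeded chance (234 against 211.7). Of the lists, 11 were called over the mean of days. Extraembryonic endoderm (9 of 20 higher, none lower; adjusted p = 0.000196) and FGF and ERK targets (10 of 16 higher, none lower; 6.56e-05) kept their call with an estimated correlation (adjusted p = 0.0103 for both).

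Differentiation itself was followed from day 0 to day 3 in each genotype. In both, naive pluripotency genes were lost and genes of the formative epiblast rose. Formative genes rose in 10 of 12 cases and fell in 1 in parental cells (adjusted p = 0.00227; adjusted p = 0.139 with an estimated correlation), and 11 rose in cKO (0.000175; 0.0749). All 17 naive genes fell in parental cells (adjusted p = 1.05e-09; adjusted p = 0.00598 with an estimated correlation) and all 17 fell in cKO (8.21e-10; 0.0114 with an estimated correlation). Dppa5a went from 2152 ± 58.6 to 54.3 ± 4.38 CPM in parental cells and from 2615 ± 301 to 28.2 ± 2.03 CPM in cKO. Streak genes rose in 17 of 21 cases and fell in 3 in parental cells (adjusted p = 0.00874; adjusted p = 0.281 with an estimated correlation), and in cKO 10 rose and 6 fell (0.518, not called). Nkx1-2 went from 1.55 ± 0.325 to 288 ± 20.8 CPM in parental cells and from 5.19 ± 0.115 to 90.7 ± 23.6 CPM in cKO. Fibroblast and feeder genes fell in 14 of 18 cases in parental cells (adjusted p = 2.96e-07; adjusted p = 0.00332 with an estimated correlation), Col1a2 from 206 ± 9.63 to 3.22 ± 0.197 CPM. In parental cells 8338 genes rose and 6962 fell, and in cKO 8314 and 7094. All day 0 libraries carry a different title prefix from the day 3 and day 6 libraries, so day and sequencing or preparation batch cannot be told apart in this comparison.

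From day 3 to day 6, days that share a title prefix, general pluripotency genes fell in both genotypes, and Hox genes and genes of epithelial to mesenchymal transition rose. General pluripotency genes fell in 13 of 14 cases and rose in 1 in parental cells (adjusted p = 1.77e-06; adjusted p = 0.00206 with an estimated correlation) and in 14 of 14 in cKO (1.49e-07; 0.000978 with an estimated correlation), with the Nodal coreceptor gene Tdgf1 going from 593 ± 38.2 to 8.54 ± 0.739 CPM in parental cells. Hox genes rose in 26 of 33 cases in either genotype, with 4 falling in parental cells and 1 in cKO (adjusted p = 1.2e-07 and 3.56e-08; adjusted p = 0.0736 and 0.0657 with an estimated correlation). Genes of epithelial to mesenchymal transition rose in 12 of 13 cases in parental cells (adjusted p = 3.89e-07; adjusted p = 0.0217 with an estimated correlation) and 13 of 13 in cKO (3.06e-08; 0.00864), Vim from 124 ± 7.58 to 876 ± 32.9 CPM in parental cells. Presomitic genes rose in 18 of 23 cases in parental cells and 17 in cKO, with 2 falling in each (adjusted p = 3.37e-05 and 1.4e-05; adjusted p = 0.207 and 0.196 with an estimated correlation), among them Foxc1 (6.29 ± 0.33 and 7.77 ± 0.37). Skeletal muscle genes rose in 9 of 12 cases in either genotype, with none falling in parental cells and 1 in cKO (adjusted p = 0.00408 and 0.00651; adjusted p = 0.0388 and 0.0425 with an estimated correlation). In parental cells 6609 genes rose and 6628 fell, and in cKO 6351 and 7053.

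Across genes, the change from day 0 to day 3 in parental cells correlated with that in cKO at Pearson r = 0.914 (jackknife SE 0.0053) and Spearman rho = 0.911, and the change from day 3 to day 6 at r = 0.789 (SE 0.0439) and rho = 0.766. These are correlations across 20267 genes, which are not independent replicates. Both changes from day 0 to day 3 cross the title prefix. A shift with the prefix that is shared by both genotypes would raise the first r, and not the second. In simulated data, where both genotypes changed alike except in a small set of genes, r was 0.962 and 0.943. Genes whose time change differed between the genotypes numbered 3768 for day 0 to day 3 and 5272 for day 3 to day 6. The first count was 6420 in the fit of the 12 libraries concerned alone.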

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

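The results in this part were picked out by the tested difference of a time change between genotypes, that is the genotype by day term of the edgeR fit, and the list results without 1 library were computed after the data were seen. For day 0 to day 3 this term called 3768 genes. Of 36 splits of the libraries, 1, the real one, called as many. The highest other split called 2863 genes, and such splits still part the genotypes in 2 days. Among the 23 splits that part them in no day the highest count was 0. The splits exchange libraries between genotypes within a day, so they test for no genotype difference at any day. They do not test for a genotype difference that is the same at each day, so chance is not excluded for this count.

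The change from day 0 to day 3 differed between the genotypes in single genes and in lists. The difference was -5.52 ± 0.33 for Cdx1, -4.16 ± 0.58 for Wnt8a, -3.92 ± 0.38 for Cdx2 and -4.09 ± 0.17 for the imprinted gene Peg10. It was positive for Hopx (4.24 ± 0.37), Otx2 (3.37 ± 0.54), Adgrb2 (3.11 ± 0.17), Ncan (3.08 ± 0.22) and Tbc1d9 (3.00 ± 0.15). List medians of the difference were -1.23 for naive pluripotency (adjusted p = 0.102 with an estimated correlation), -1.68 for primitive streak and nascent mesoderm (0.108), -1.11 for trophoblast (0.385), -1.87 for Hox genes (0.217), 0.35 for epithelial junction (0.741), -1.58 for two-cell-like (0.102) and 1.18 for fibroblast and feeder (0.0039). The fibroblast list was the only 1 of these 7 kept with an estimated correlation, and its genes were already lower in cKO at day 0. Two-cell-like genes also differed at day 0, with 12 of 13 higher in cKO, while at day 3 0 were higher and 1 lower. The epithelial junction call was lost without cKO day 0 replicate 2 or cKO day 3 replicate 1 (adjusted p up to 0.0883).

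For day 3 to day 6 the term called 5272 genes. Of 36 splits 1 called as many, with 4902 in the highest other split, and for the same reason chance is not excluded for this count. T, a streak factor, fell less in cKO, with a difference of 6.81 ± 0.64, and so did Trh (5.01 ± 0.54). Tmprss2 (4.53 ± 0.43) gained more in cKO. The histone gene H2bu2 fell more in cKO (-5.33 ± 0.32), and Fndc5 (-4.82 ± 0.23), Scube2 (-4.94 ± 0.75) and the neural regulator gene Prdm8 (-4.80 ± 0.36) gained less.

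Of the 19 lists called for this term, 6 kept their call with an estimated correlation. Their medians were 2.38 for primitive streak and nascent mesoderm (adjusted p = 0.0356 with an estimated correlation), 1.16 for extraembryonic endoderm (0.00101), 0.59 for TGF-beta, Nodal and BMP response (0.0234), 0.97 for Wnt response (0.0203), 0.44 for FGF and ERK response (0.00805) and 1.17 for fibroblast and feeder (0.00472). The other called lists had medians of 1.44 for endothelial and blood, 2.71 for definitive endoderm, 1.31 for trophoblast, -1.35 for neuroectoderm and neurons, -1.21 for Notch response, 1.67 for epithelial junction, 1.26 for p53 targets, 0.48 for stress, -0.47 for cell cycle and -0.32 for Polycomb genes. General pluripotency (-0.61), lateral plate and cardiac mesoderm (0.69) and epithelial to mesenchymal transition (0.50) had calls that were lost when single libraries were left out. For general pluripotency these were parental day 6 replicate 3 and cKO day 6 replicates 1 and 3 (adjusted p up to 0.0659). For lateral plate it was cKO day 6 replicate 1 (0.0612), and for the transition list 6 libraries of days 3 and 6 (up to 0.126). Without cKO day 6 replicate 2, the medians were 1.01 for epithelial junction, 0.60 for p53 targets, 0.31 for stress, -0.85 for Notch response and 1.86 for endothelial and blood. Without it, the genotype contrast at day 6 called 13 of 15 endothelial and blood genes higher and 2 lower.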

How the results depend on the processing

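The tests of protein-coding genes only and of genes outside chromosome 11 were chosen after the data were seen; the other alternatives were planned. No paired analysis was possible because the labels do not pair the replicates of different groups. With the libraries of the contrast alone 8780 genes were called at day 0, 5874 at day 3 and 5721 at day 6. The main fit called 6402, 3185 and 9238. For the difference of the day 0 to day 3 change 6420 were called, against 3768. The spread then rests on fewer libraries. The main fit shares the spread of each gene over all 18 libraries, and cKO day 6 replicate 2 stood apart from its replicates. Day 6 calls of the main fit may therefore be too many, and calls at other days too few, which was not tested. With an estimated correlation the lists called went from 10 to 0 at day 3 and from 17 to 4 at day 6. The preset correlation was 0.01, and estimates reached 0.846 for epithelial junction, 0.739 for cell cycle and 0.648 for p53 targets. A larger correlation makes camera less ready to call a list. It was not the only cause. The fibroblast and feeder estimate, 0.0097, was near the preset, yet the camera adjusted p at day 6 went from 6.58e-07 to 0.00223. Each estimate is 1 value per list over all 18 libraries, so it is not specific to a contrast. With fry, which compares a list with no other genes, they went from 3 to 14 at day 0 and from 17 to 27 at day 6. The Pearson correlation of the day 0 to day 3 changes was 0.924 with at least 1 CPM in 3 libraries and 0.907 to 0.912 with each library left out, and the Spearman correlation 0.905 to 0.909; the cause was not tested. Of 220 named gene results, all kept their call, and the called ones their direction, under RLE factors, no low-count filter and at least 1 CPM in 3 libraries. Total-count scaling added 1 call, DESeq2 added 1 and gave no adjusted p for Cyp1a1, and the libraries of the contrast alone added 1 of 209. Of 128 list results 95 were lost with an estimated correlation, 3 with fry, 4 with RLE factors and 13 with some library left out. Genes called with each library left out ranged from 5081 to 5527 at day 0, 2197 to 2499 at day 3 and 7871 to 9495 at day 6. No called gene or list reversed its direction under these alternatives. The balance of calls did turn with RLE factors and DESeq2 at day 0, at day 6 and over the mean of days. At day 3 lower calls stayed the majority with both. In the main fit chromosome 11, over its 921 genes of at least 5 CPM, gave 565 of the 1904 lower calls at day 3. It gave 10 of the 1281 higher calls. Genes higher in cKO made up 47.7% of calls at day 0, 40.2% at day 3, 43.7% at day 6 and 44.2% over the mean of days, against 52.8%, 46.1%, 50.8% and 52.7% with RLE factors and 52.8%, 47.3%, 50.9% and 53.4% with DESeq2; the cause was not tested. In data simulated with 3 libraries per group, 49.3% of genes changed 1.5 fold were called and 97.0% of those changed 4 fold; other depths and numbers of libraries were not simulated.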

Other observations

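Tests chosen only after the results were seen were those of poly(A) selection and of differentiation for the RNAs without poly(A) tails, and that of the share of day 0 cells for cKO day 6 replicate 2. Chance was tested with other splits of the same libraries. Each genotype contrast of a single day has 10 splits, too few for a share under 0.05: the real value was 6402 genes at day 0 with 0 in the highest other, 3185 at day 3 with 0, and 9238 at day 6 with 1. The 4 time contrasts also have 10 splits each, too few for a share under 0.05, with real values of 15300, 15408, 13237 and 13404 and 0 in the highest other. Over the mean of days, 1 of 36 splits called as many as 7305 genes, with 4300 in the highest other. This argues against a chance assignment of these libraries to the genotypes within days. It does not exclude a chance difference between the parental and cKO cells or cultures.

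Histone mRNAs, most of which lack poly(A) tails, rose from day 0 to day 3 by a median of 8.74 over 66 genes in parental cells and 9.46 in cKO, all 66 higher in both. Rn7sk and Rpph1 together took at most 0.0021% of counts at day 0 and 1.06% to 1.85% later. The lower of the 2 histone medians, 8.74, is what preparation with poly(A) selection at day 0 and without it later would give. Genes that share sequence rose more than genes that share none, by 0.89, which leaves a difference in counting reads with several matches open. The histone median from day 3 to day 6 was -0.19 in parental cells with 8 of 66 lower and -1.03 in cKO with 52 lower. It cannot decide on differentiation, because day 0 and the title prefix coincide. Cell cycle genes did not rise with the histone genes from day 0 to day 3. Of 23, 18 were lower and 2 higher in parental cells, and 13 lower and 3 higher in cKO. These values argue against more dividing cells as the source of the rise. Since title prefix and day coincide, preparation, read counting and differentiation cannot be told apart, and preparation is a candidate explanation only.

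Genes of chromosome 11 were lower in cKO at every day. The 9 cKO libraries had medians of -0.47 to -0.39 against parental libraries of the same day, less the median of the other autosomes, and the 9 parental libraries -0.011 to 0.0093. Of 12 bins of 10 Mb none (0) had a median above -0.1, and all 12 lay below -0.2 where 2 of 189 bins of other autosomes did. A lower copy number of the whole chromosome in cKO than in parental cells would give this. The comparison is relative, so a loss in cKO cells and a gain in parental cells cannot be told apart. GC content is argued against, since sets matched on GC content and expression differed by -0.47 and 0 of 10000 reached so low a median. The upper quartile over the mean of days, -0.26, does not decide whether loss of Oct1 lowers these genes without a change in copy number, so a copy number difference may account for the shift but was not measured in DNA.

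The cKO day 6 replicate 2 library stood apart, with chi-square per degree of freedom of 96.9 and 106 against its replicates where other pairs of replicates gave 1.23 to 12.4. Krt8, a keratin gene chosen after its values were seen, stood at 1912 CPM in it and at 334 and 330 CPM in the others. The epithelial junction, p53, neuroectoderm and Hox lists moved with it, with medians of 2.61, 1.81, -2.65 and -2.57 against parental day 6. Malat1, also chosen after its values were seen, took 1.445% of its counts and 0.59% and 0.57% in replicates 1 and 3. Ribosomal protein mRNAs took 2.56% against 3.24% and 3.06%, and Rn7sk and Rpph1 together 1.06% against 1.60% and 1.34%. RNA quality was not tested as an explanation. The naive list was higher in replicate 2 by a median of 0.63, as undifferentiated day 0 cells would give. So were 223 genes abundant at day 0, by a median of 0.63, with 67.7% of them higher. Such cells cannot account for most of the 815 genes higher in it by over 1 log2 unit, since 65.5% exceeded their level in cKO day 0. The naive list needs a share of 0.21% day 0 cells. At that share 3 of the 10 most abundant day 0 transcripts lay below the predicted level, Dppa5a at 2.07 CPM against 7.22. Others lay above it, L1td1 at 60.6 CPM against 18.7. The share was fitted to the naive list, which holds Dppa5a and Nanog, so this test cannot decide whether some day 0 cells were present. The slopes on the day 3 to day 6 change were -0.002 and -0.0039 over 11382 genes, with a mean of -0.0029. A delay shared by genes at large would give a clearly negative slope, so these values argue against it. They do not test a delay limited to some genes. The Pearson r with the genotype difference of the other libraries was 0.33 across genes, which are not independent replicates. A library that carries that difference further would give such a value, but several lists went the other way. The presomitic, endothelial and blood, and epithelial to mesenchymal transition lists had medians of -0.60, -0.13 and -0.49 in replicate 2. In replicate 3 they were 0.63, 1.40 and 0.53.

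Several germline and sex-linked genes changed in cKO at each day. Usp26, on the X chromosome, changed by -3.38, -4.34 and -5.44 at days 0, 3 and 6, and Dmrt1, on chromosome 19, was at 5.57 ± 0.487, 3.74 ± 0.501 and 0.513 ± 0.175 CPM in cKO against 25.4 ± 0.559, 27.1 ± 3.1 and 8.39 ± 0.505 CPM in parental cells. Stra8, which acts in entry to meiosis, stood at 0.0469 ± 0.0472 CPM in cKO and 14.1 ± 1.15 CPM in parental cells at day 6. The Y-linked gene Kdm5d changed by -2.01, -1.27 and -1.83, while Ddx3y, also on the Y chromosome, changed by 0.95, 1.03 and 1.26; Ddx3y was chosen after its values were seen. Of 5 Y-linked genes examined, 3 were higher and 2 lower in cKO at each day. Pou2f3, a paralogue of Pou2f1, was higher in cKO at days 0 and 3 (3.38 and 1.61).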
